A study of Homo sapiens with 21 samples.

How the data were processed

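Total RNA was depleted of rRNA and sequenced from HEK293 (WT, TNRC18 KO and TNRC18 L760A), SNU-1 (WT and KO) and HT-29 (WT and KO), 3 libraries per group and 21 in all, per the labels. The edits used a pair of guide RNAs for partial deletion or knockout and a guide with a donor strand for the substitution, per the labels' protocols. The signal values were made by the authors as reads per gene divided by a size factor for each library: every value above 0 was a whole multiple of the smallest value in its column, within a tolerance of 0.01, so whole reads were recovered from the deposited tables. In HEK293 WT replicate 1 that smallest value lay close to 1, where multiples are less telling, and its reads were recovered in the same way. The submitters' processing notes name STAR 2.4.2, Salmon 1.4.0, Picard 2.22.4, FastQC 0.11.9 and DESeq2 1.38.2 with GRCh38 and hg38. Tables were deposited for each line separately, with 17987, 14430 and 15066 genes, and how genes were left out of them was not stated. Values for transposable elements were not analysed here. Depth was 3469846 to 7650356 reads per HEK293 library, 5954702 to 7267320 in SNU-1 and 2485915 to 3870183 in HT-29.

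Raw counts were not at hand, so the plan's branch for scaled values was followed. Values were taken as log2(value + 1) and tested with limma 3.58.1 (trend and robust variance, R 4.3.3) for genes with a mean of at least 1 in a group, with a Benjamini-Hochberg threshold of 0.05. HEK293 was fitted with all 9 libraries, and KO and L760A were each compared with WT and with each other. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and again with the correlation between genes estimated. List calls in the text are those of camera. The planned fry test, which does not set a list against the other genes, called more lists in each comparison and is reported in part only. A gene counted as separated when the 3 libraries of a group lay outside the range of the other group.

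The 27 lists, fixed before values were seen, were: LTR-derived genes, genes reported with an LTR promoter or enhancer, H3K9 methylation with HP1, HUSH and TRIM28 silencing, SIN3, HDAC and NCoR subunits, interferon-stimulated genes, nucleic acid sensing, antigen presentation, cancer-testis and germline genes, clustered protocadherins, ZNF genes, HOX genes, neighbours of TNRC18 on 7p22, cell cycle, p53 targets, ATF4 and unfolded protein response, cholesterol biosynthesis, MYC and ribosome biogenesis, epithelial, mesenchymal, neuronal, intestinal and gastric genes, kidney and adrenal markers, blood and immune markers, histone genes, mitochondrial genes and ribosomal protein genes. Older symbols were matched only where they are not the current symbol of another gene.

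Genes were named by rule: TNRC18; in each comparison the 10 genes higher and 10 lower with the largest fold among those with adjusted p under 0.05, a log2 fold change of at least 1 in size, separated libraries, a mean of at least 5 in the higher group and an official symbol; up to 4 members of each list with the smallest p; and, for shared changes, the 10 per direction with the largest smallest change. Some genes that the rule names are not reported here. MCM3 and CDC20 in HT-29 were named outside the rule, to show cell cycle members that were lower. A fold against a group without reads was given as a floor that allows 3 reads over the group, and a gene with 1 to 3 reads there as a ratio of pooled reads with a 95% exact binomial interval.

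Positions and transcript types came from GENCODE v29, and 83.6, 84.9 and 84.6% of the genes in the HEK293, SNU-1 and HT-29 tables had a position. Chromosome medians used genes with a mean of at least 20, and windows were 10 Mb with at least 10 genes. Intervals came from 1000 bootstrap draws of genes, taken as independent. Overlaps of called genes were set against independent lists, and for the HEK293 pair against 100 simulations with shared controls.

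Alternatives planned beforehand were quantile normalization, no filter or a mean of at least 5, a pseudocount of 0.1, a replicate block, 6 libraries in place of 9, leaving out each library, and a log2 fold change of at least 1 in size. Added after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, total reads as scaling, removal of trends with GC content and length, and removal of the running median along chromosomes, with windows that shrink at chromosome ends or with the nearest full window there. Medians with position removed in the results use full windows. The plan left the interaction between lines untested for tables normalized separately; it was added on recovered reads with edgeR. Replicate numbers did not pair libraries, as no comparison had every same-number correlation above 0.1 (HEK293 KO -0.043 to 0.163).

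On simulated changes of 1.5, 2 and 4-fold the limma test found 47.8, 74.6 and 95.5% for HEK293 KO, 46.3, 68.7 and 90.9% for L760A, 65.7, 79.1 and 97% for SNU-1, 44.8, 65.7 and 90.9% for HT-29 and 44.8, 67.2 and 86.4% for L760A against KO, with false shares of 4, 7.4, 6.4, 2.9 and 9%, so that a false share above the 5% aimed for was seen in 3 of them. Each comparison had a single simulated set with 200 changed genes, while the real comparisons called 31.9 to 58.7% of genes. The shares found therefore do not give the power of the real tests, and the false shares rest on 4 to 13 genes. Pairs of libraries within groups were checked for copies, and the 21 pairs differed by more than counting error (chi-square per degree of freedom 1.67 to 7.97). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.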

Results

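RNA from 21 libraries of 3 human cell lines was compared: embryonic kidney HEK293, gastric carcinoma SNU-1 and colon adenocarcinoma HT-29. Each line had 3 unedited (WT) libraries and 3 libraries labelled TNRC18 KO, and HEK293 had 3 more from cells with the L760A substitution in TNRC18, placed by the submitters in a region that binds Sin3 and HDAC proteins. TNRC18 is a chromatin reader tied by the submitters to H3K9me3 and the silencing of endogenous retroviruses. The tables held 17987 genes for HEK293, 14430 for SNU-1 and 15066 for HT-29, as reads divided by a size factor, and depth ran from 2485915 to 7650356 reads per library. Expression is given in these scaled reads as mean ± SD with n = 3 libraries per group. Log2 fold changes were taken on log2(value + 1) and understate the change of genes with few reads, and adjusted p-values are from limma. Values of single genes keep any shift of their chromosome unless position is said to be removed.

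TNRC18 itself was called lower in the KO-labelled libraries of SNU-1, in every setting tried. There it averaged 1533.8 ± 7.1 (range 1525.8 to 1539.4) against 2488.8 ± 61.4 (2420.3 to 2539.0) in WT, 1.62-fold lower (log2 fold change -0.70, adjusted p = 1.27e-17, n = 3 each). In HEK293 it stood at 1682.3 ± 172.9 (1482.7 to 1785.9) in the KO-labelled libraries, 1476.0 ± 61.4 (1433.8 to 1546.4) in L760A and 1471.9 ± 184.2 (1266.8 to 1623.1) in WT, with log2 fold changes of 0.20 (adjusted p = 0.0655) and 0.01 (adjusted p = 0.936). The HEK293 direction turned with the setting: removal of GC content and length trends gave -0.22 for the libraries labelled KO (adjusted p = 0.000382) and -0.14 for L760A (0.0276), while quantile normalization gave 0.44 for the former (0.000665). In HT-29 it was 2355.0 ± 126.0 (2281.1 to 2500.5) against 2240.0 ± 16.8 (2221.2 to 2253.5), log2 fold change 0.07 (adjusted p = 0.152), or 0.24 with position removed (adjusted p = 3.66e-07). The edit was made with a pair of guide RNAs for partial deletion or knockout and was checked by the submitters on PCR products, so a transcript that lost a few exons would still be counted over the whole gene. TNRC18 RNA therefore does not show whether the HEK293 and HT-29 libraries lacked the protein, and the groups are called "labelled KO" for that reason. Directions below are those of the labelled group against WT.

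**Figure D1:**
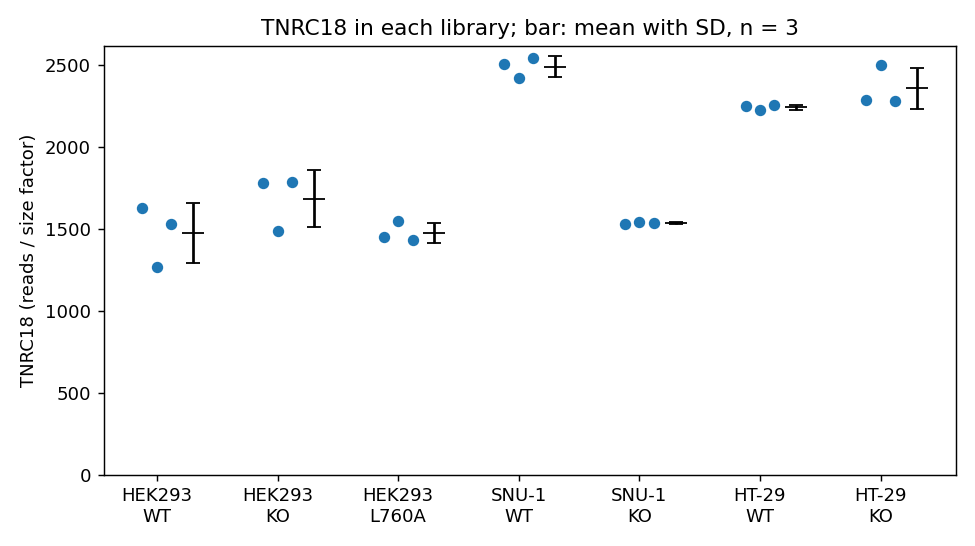
TNRC18 in every library by group, in reads divided by the size factor. Points are libraries, lines the mean with SD, n = 3 per group.

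In HEK293 libraries labelled KO, MYC and the ribosome biogenesis genes fell. The membrane peptidase gene DPP4, known in renal and intestinal epithelium, averaged 49.4 ± 5.21 against 0.522 in WT (n = 3 each, adjusted p = 1.24e-07). MYC, the growth regulator that drives ribosome production, fell 7.79-fold, from 1201 ± 42.5 to 153.6 ± 9.92. The matrix gene FN1 rose 8.11-fold, from 326.5 ± 26.9 to 2652 ± 118, and the neuronal intermediate filament gene NEFM, which WT HEK293 cells carry at a high level, fell 9.60-fold from 1134 ± 67.9 to 117.9 ± 16.3.

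Single genes of varied function had other large gains in the HEK293 libraries labelled KO. NRG3, a neuregulin ligand of ERBB4, rose 22.2-fold (4.41 ± 3.84 to 84.9 ± 2.15), the tubulin carboxypeptidase gene AGBL2 21.7-fold and the mitochondrial acyl-CoA synthetase gene ACSS3 21.1-fold (6.86 ± 4.47 to 147.9 ± 16.6). Genes with 1 to 3 WT reads are given as ratios of pooled scaled reads with 95% exact binomial intervals: a range of 21.7 to 667 for DPP4, 38.8 (12.9 to 191) for the retinaldehyde dehydrogenase gene ALDH1A1 and 48.1 (12.9 to 404) for the antiviral TRIM22. CRHR1, the receptor for corticotropin-releasing hormone, had no WT read and was at least 20.5-fold higher. SSU72P4 and SSU72P7 also rose, at ratios of 42.6 and 21.0, but near-identical copies leave their reads uncertain. These intervals and floors cover counting error only.

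The largest losses in the same libraries were again single genes of varied function. FAM155A, a subunit of the NALCN sodium leak channel, fell from 77.8 ± 3.37 to 0.270 ± 0.467, a pooled ratio of 230 (40.9 to 9.11e+03), and the synaptic adhesion gene NRXN3 fell with a ratio of 181 (32.0 to 7.17e+03). The testis antigen gene MAGEB2 went from a mean of 44.5 to no reads and the proteoglycan enzyme gene XYLT1 from 35.4 ± 9.43 to no reads, at least 43.2-fold and 35.8-fold lower. SIM1, a hypothalamic transcription factor, had a ratio of 93.9 (16.5 to 3.74e+03), and the actin bundler LCP1 fell 15.4-fold (138 ± 7.20 to 8.49 ± 3.31). TPTEP1, a phosphatase pseudogene, had a ratio of 32.2 (8.59 to 271). SLC2A3P1 (at least 46.5-fold lower) and the readthrough SLX1B-SULT1A4 (log2 fold change -4.71, adjusted p = 0.0318) share sequence with other genes and remain uncertain.

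Ribosome production was the most uniform change in HEK293 libraries labelled KO. All 26 tested genes of the MYC and ribosome biogenesis list were lower (0 higher, 26 lower; the same 26 when adjusted over the list alone), among them the nucleolar chaperone NPM1 (log2 fold change -1.61, 8932 ± 342 to 2919 ± 154), the rRNA transcription regulator MYBBP1A (-1.81) and the mitochondrial chaperone HSPD1 (-1.45). The list median was -1.24 (camera adjusted p = 3.12e-22). Ribosomal protein genes, which code for the particle itself, had 72 lower, 1 higher and 5 not called of 78 (73 lower over the list alone, median -0.67, camera adjusted p = 6.4e-24). RPL8 fell from 7085 ± 309 to 2902 ± 90.5 (-1.29), RPL7 by 1.20 and RPL5 by 0.87, and RPL22 went from 1451.5 ± 49.2 to 711.4 ± 24.0. RPL8, RPL7 and MYC lie on chromosome 8, NPM1 on chromosome 5 and RPL5 and RPL22 on chromosome 1. The medians of these chromosomes were -0.416, -0.358 and -0.266 in these libraries. The ribosomal protein call was lost at adjusted p = 0.0832 with an estimated correlation between genes. Cell cycle genes were lower as well, 21 lower, 3 higher and 13 not called of 37 (the same alone, median -0.32, camera adjusted p = 2.04e-05). Their call was lost under quantile normalization with a median of -0.16 and adjusted p = 0.0586. The replication helicase genes MCM7 and MCM4 stood at -1.01 and -0.85 and the mitotic genes CDC20 and CCNB1 at -0.88 and -0.84. All of these lie on lowered chromosomes: MCM7 on chromosome 7, MCM4 on 8, CCNB1 on 5 and CDC20 on 1. The chromosome medians were -0.576, -0.416, -0.358 and -0.266 in that order.

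Antiviral, matrix and p53 genes rose in HEK293 libraries labelled KO. OAS3, which activates RNase L on double-stranded RNA, rose 5.37-fold from 41.96 ± 5.08 to 228.8 ± 7.15, and the membrane restriction factor IFITM3 5.33-fold from 19.8 ± 2.57 to 110.2 ± 15.3. PARP14 rose 2.26-fold and LGALS3BP had a log2 fold change of 1.15. Interferon-stimulated genes counted 22 higher, 1 lower and 12 not called of 35 (23 and 1 alone, camera adjusted p = 5.3e-05). Of 28 mesenchymal genes 17 were higher and 5 lower, with 6 not called and the same counts alone (median 0.48, adjusted p = 0.00109, lost at adjusted p = 0.0806 with an estimated correlation), including the collagen gene COL5A1 (2.37), SPARC (2.56, 96.98 ± 4.82 to 575.5 ± 25.6) and the gelatinase MMP2 (2.91). Of 30 p53 targets 17 were higher, 4 lower and 9 not called (18 and 4 alone, median 0.28, adjusted p = 0.00464, lost at adjusted p = 0.064 with an estimated correlation). The damage sensor DDB2 rose 3.65-fold (257.6 ± 15.3 to 941.6 ± 20.9), TP53INP1 by a log2 fold change of 1.02, BTG2 by 0.87 and PMAIP1 by 0.68.

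Genes next to TNRC18 on 7p22 fell in HEK293 libraries labelled KO, while TNRC18 was not called in the main test. The direction of TNRC18 turned with the setting, to -0.22 (limma adjusted p = 0.000382) with GC content and length removed. Of 20 neighbours 17 were lower, 2 higher and 1 not called (the same alone, median -0.71, camera adjusted p = 4.53e-06, lost with position removed, median -0.078 and adjusted p = 0.822), and the forkhead factor FOXK1 fell from 1570 ± 53.5 to 654.1 ± 26.9 (-1.26), AIMP2 by 1.45 and KDELR2 by 0.84. The lower level reached over the whole chromosome: the 580 chromosome 7 genes had a median of -0.58 (95% interval -0.64 to -0.52), with 84.1% below 0. Cholesterol synthesis genes counted 15 lower, 3 higher and 6 not called of 24 (5 higher and 15 lower alone, median -0.40, adjusted p = 0.0156, lost at adjusted p = 0.0806 with an estimated correlation, and also under quantile normalization, GC correction and position removal), with SQLE at -1.25. HOX genes, which set position along the body axis, counted 19 higher, 8 lower and 11 not called of 38 (the same alone, median 0.41, adjusted p = 0.0361, lost at adjusted p = 0.347 with an estimated correlation). HOXB8 rose by 1.58 and HOXB3 by 0.95, while HOXA9, which lies on chromosome 7, fell by 0.82.

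The remaining lists were not called in HEK293 libraries labelled KO, although single members passed. LTR-derived genes gave 3 higher, 1 lower and 3 not called of 7 (median 0.39, camera adjusted p = 0.492), with the envelope gene ERVW-1 at 8.33 ± 2.64 against 1.25 ± 0.651 (2.05, adjusted p = 0.00739) and ERVK3-1 at -0.58. Genes reported to use LTR promoters gave 6 higher, 1 lower and 7 not called of 14 (median 0.38, adjusted p = 0.129), with the granzyme inhibitor SERPINB9 at 2.01, MID1 at 0.93 and DHRS2 at -1.12. H3K9 silencing genes gave 11 higher, 13 lower and 13 not called of 37 (median 0.0015, adjusted p = 0.986), and that sign turned with the correction for GC content. Among the HP1 genes CBX5 had 0.92 and CBX3 -0.69, values from which chromosome position was not removed. SIN3, HDAC and NCoR subunits gave 7 higher, 9 lower and 13 not called of 29 (9 and 9 alone, median -0.0050, adjusted p = 0.868, sign turned by quantile or total-read scaling), with RBBP7 at 0.72 and HDAC3 at -0.81. Nucleic acid sensors gave 4 higher, 3 lower and 11 not called of 18 (median -0.038 but mean 0.33, median positive under 4 other scalings, adjusted p = 0.868), with DDX58 at 1.12 and ADAR at -0.38, the last not lower with position removed.

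Antigen presentation gave 12 higher, 7 lower and 7 not called of 26 in the same comparison (median 0.32, camera adjusted p = 0.441), with HLA-DPA1 at 1.57 and CANX at -1.09. Germline genes gave 5 higher, 4 lower and 4 not called of 13 (median 0.30 but mean -0.08 and median -0.054 after GC correction, adjusted p = 0.901), with PRAME at 1.75 and LIN28B at -1.38. Clustered protocadherins gave 4 higher, 0 lower and 19 not called of 23 (3 higher alone, median 0.76, adjusted p = 0.164), with PCDHGB5 at 1.01 and its reads uncertain. ZNF genes gave 122 higher, 99 lower and 206 not called of 427 (median 0.061 but mean -0.0054, adjusted p = 0.52), with ZNF608 at 1.36 and ZNF121 at -0.93. ATF4 and unfolded protein genes gave 4 higher, 13 lower and 10 not called of 27 (median -0.26, adjusted p = 0.0546), with SLC7A5 at -1.08 and ATF4 at -0.82. Histone genes gave 11 higher, 20 lower and 29 not called of 60 (10 and 20 alone, median -0.16 but mean 0.019 and median 0.14 after GC correction, adjusted p = 0.147), with HIST1H3F at 2.94 and HIST2H3A at -1.16, both from copies hard to tell apart.

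Lists of tissue markers were not called in HEK293 libraries labelled KO, and single members passed. Neuronal genes gave 5 higher, 11 lower and 10 not called of 26 (median -0.31, camera adjusted p = 0.164), with the neurofilament gene NEFL at -1.17 and the vesicle gene SYP at -1.09. Epithelial genes gave 8 higher, 2 lower and 10 not called of 20 (6 and 2 alone, median 0.60, adjusted p = 0.127), with CDH1 at 1.19 and KRT8 at 0.80. Intestinal genes gave 4 higher, 1 lower and 2 not called of 7 (median 0.68, adjusted p = 0.296), with the stem cell gene LGR5 at 0.85 and CDH17 at a pooled ratio of 43.6 (7.38 to 1.77e+03). Gastric genes gave 2 higher, 0 lower and 5 not called of 7 (median 0.50, adjusted p = 0.296), with GATA6 at 0.58 and SOX2 at 114.8 ± 8.90 against 57.8 ± 11.8. Kidney and adrenal markers gave 6 higher, 2 lower and 4 not called of 12 (median 0.28, adjusted p = 0.441), and none of 4 immune genes was called. Of 13 mitochondrial genes 2 were higher and none lower, with none alone (median 0.21, adjusted p = 0.164), and their share of reads was 2.15 ± 0.35% against 1.60 ± 0.333% in WT.

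Across all 17960 genes tested in HEK293 libraries labelled KO, 4809 were higher and 4746 lower at adjusted p under 0.05, with 50.3% of the called genes higher. Total reads as the scaling raised that share to 63.7%, so the balance of gains and losses rested on the size factors. All 3 libraries of each group were separated without overlap for 57.8% of genes, where chance alone gives 10%. The labels do not say that replicates were separate cultures, so the p-values here measure spread between these libraries, which may be technical. They also do not say how many edited clones were grown, so a difference between groups can belong to a clone.

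**Figure D2:**
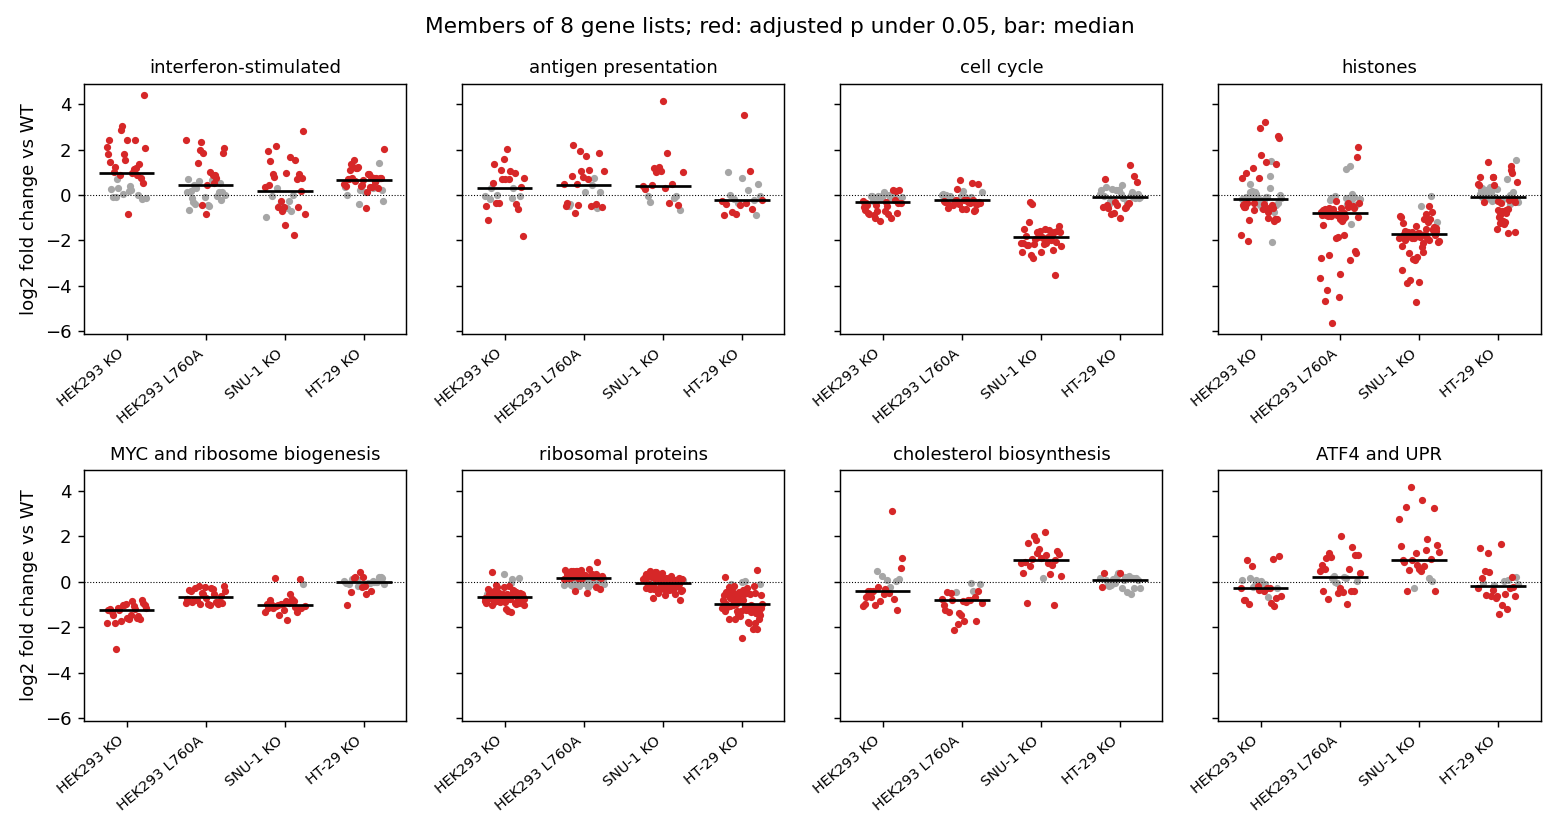
Log2 fold changes of the members of 8 gene lists in each comparison against WT. Red marks adjusted p under 0.05 by limma and the bar is the list median.

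Several cytokine genes were among the largest gains in HEK293 L760A libraries, although no cytokine list was tested. CXCL8, a neutrophil attractant and NF-kB target, rose 28.9-fold, from 1.11 ± 1.18 to 53.5 ± 7.68 (n = 3 each, adjusted p = 5.09e-08), and CXCL1, which acts on the same receptor, rose from 0.585 ± 0.516 to 80.8 ± 2.89, a pooled ratio of 134 (36.6 to 1.11e+03). TNF reached 37.6 ± 8.68 with a ratio of 41.1 (13.7 to 202), and TNFRSF9, a costimulatory receptor of lymphocytes, rose 35.1-fold to 111.8 ± 10.5. The insulin receptor substrate IRS4, by which HEK293 cells pass on insulin signals, fell 44.4-fold from 507 ± 37.4 to 11.1 ± 5.22.

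Further cytokine genes rose with L760A: IL32 13.7-fold (9.29 ± 2.02 to 137.9 ± 2.33, adjusted p = 7.63e-11), CXCL3 11.8-fold, the monocyte attractant CCL2 by a log2 fold change of 3.40 and the lymphocyte growth factor IL7 with a ratio of 44.7 (12 to 375). The hair keratin-associated gene KRTAP19-1 rose 14.5-fold and the ion exchanger SLC24A2 with a ratio of 24.7 (8.1 to 123). The largest fitted fall was HSPA1A, 259-fold from 959.8 ± 136 to 4.05 ± 3.52 (adjusted p = 0.000254), but its near-identical copy HSPA1B leaves the reads uncertain. HIST1H2BG fell 49.2-fold (330.5 ± 18.3 to 5.88 ± 1.71, adjusted p = 1.56e-18) and CDR1, the locus of a circular RNA of neurons, 35.8-fold. TMEM47, a junction protein, had a ratio of 82.0 (27.7 to 400) and FLRT2, a guidance and adhesion gene, 81.2 (22.1 to 676). JAKMIP2 and FAM162B had no L760A reads and were at least 29.7-fold and 26.3-fold lower. IPO5P1, with a ratio of 150 (26.5 to 5.94e+03), and SLC2A3P1, at least 47.7-fold lower, are pseudogenes with shared sequence.

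Cholesterol synthesis genes fell with L760A, 20 lower, 0 higher and 4 not called of 24 (22 lower alone, median -0.82, camera adjusted p = 1.08e-14). HMGCS1, the entry enzyme of the pathway, fell 4.32-fold from 1119 ± 49.4 to 258.4 ± 16.1, and SQLE had a log2 fold change of -1.72. All 26 MYC and ribosome biogenesis genes were lower, as they were alone (median -0.67, adjusted p = 1.08e-14, lost at adjusted p = 0.0661 with an estimated correlation), with ODC1 at -0.96, HSPD1 at -0.90, NCL at -0.79 and NPM1 at -0.73. Histone genes counted 44 lower, 2 higher and 14 not called of 60 (48 and 2 alone, median -0.79, adjusted p = 1.08e-14, lost at adjusted p = 0.186 with an estimated correlation). Among them HIST1H2AE fell by 4.66, HIST1H1D by 2.77 and HIST1H3F at least 21.4-fold, with the caution that histone genes share sequence. Ribosomal protein genes went the other way from the libraries labelled KO: 38 higher, 4 lower and 36 not called of 78 (39 and 5 alone, median 0.16, adjusted p = 3.52e-05, lost at adjusted p = 0.579 with an estimated correlation), with RPS27 at 0.88, RPL31 at 0.49 and RPL7L1 at -0.51.

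Smaller list shifts with L760A touched division, body-axis and antiviral genes. Cell cycle genes counted 21 lower, 4 higher and 12 not called of 37 (22 and 5 alone, median -0.23, camera adjusted p = 0.00379, lost at adjusted p = 0.0661 with an estimated correlation, under quantile normalization with a median of -0.095 and adjusted p = 0.201, and after GC correction with -0.14 and 0.154), with PLK1 at -0.70, RRM1 at -0.66 and TOP2A at 0.47. RRM1 lies on chromosome 11 and PLK1 on chromosome 16, whose medians were -0.558 and -0.295 in L760A. HOX genes counted 16 higher, 3 lower and 19 not called of 38 (the same alone, median 0.30, adjusted p = 0.00477, lost at adjusted p = 0.329 with an estimated correlation and at 0.145 with position removed), with HOXC4 at 1.55, HOXB9 at 0.69 and HOXA10 at -0.70. Interferon-stimulated genes counted 13 higher, 2 lower and 20 not called of 35 (the same alone, median 0.42, adjusted p = 0.0172, lost at adjusted p = 0.11 with an estimated correlation and at 0.0815 under quantile normalization), with IFI6 at 73.3 ± 3.77 against 27.1 ± 6.38 (1.43), IFITM1 at 1.84 and PARP14 at 0.89. Mesenchymal genes split, 11 higher, 3 lower and 14 not called of 28 (the same alone, median 0.42, adjusted p = 0.0204, lost at adjusted p = 0.266 with an estimated correlation and at 0.0995 with position removed). FN1 rose to 1019 ± 22 (1.64) and COL3A1 by 3.05, while CTGF, a target of YAP, fell by 2.96. Of 13 mitochondrial genes 4 were higher and 9 not called (the same alone, median 0.34, adjusted p = 0.03). That call was lost at adjusted p = 0.733 with an estimated correlation and at 0.365 without WT replicate 1 (median 0.18). MT-CO1 stood at 0.95, and the mitochondrial share was 2.43 ± 0.036% of reads.

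Other lists were not called with L760A. H3K9 silencing genes gave 7 higher, 10 lower and 20 not called of 37 (median 0.064, camera adjusted p = 0.767), although TRIM28, the corepressor of KRAB zinc finger proteins, fell from 1.63e+04 ± 1614 to 9838 ± 116 (-0.73, adjusted p = 1.07e-07), and HELLS and CBX5 rose by 0.63 and 0.52. SIN3 and HDAC subunits gave 6 higher, 7 lower and 16 not called of 29 (median 0.035 but mean -0.051 and median -0.072 after GC correction, adjusted p = 0.941), with BRMS1 at -1.20. LTR-derived genes gave 1 higher, 2 lower and 4 not called of 7 (median 0.15, negative under quantile scaling, test direction down, adjusted p = 0.941), with ERVMER34-1 at -1.58. Genes with LTR promoters gave 4 higher, 2 lower and 8 not called of 14 (5 and 2 alone, median 0.077 but mean -0.12, adjusted p = 0.574), with SERPINB9 lower at a ratio of 28.7 (9.54 to 142) and DHRS2 at -2.20. ZNF genes gave 68 higher, 88 lower and 271 not called of 427 (65 and 86 alone, median 0.0076 but mean -0.19 and median -0.013 under quantile scaling, adjusted p = 0.941), with ZNF160 20.6-fold lower (47.7 ± 13.5 to 1.70 ± 1.61) and ZNF254 at -2.40. TNRC18 neighbours gave 1 higher, 4 lower and 15 not called of 20 (median -0.075, positive under quantile or total-read scaling, adjusted p = 0.506), with FSCN1 at -1.32 and AIMP2 at -0.92.

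Further lists left without a call in L760A held strong single changes. Antigen presentation gave 12 higher, 7 lower and 7 not called of 26 (14 and 8 alone, median 0.46, camera adjusted p = 0.11), with the peptide trimmer ERAP2 higher and TAPBP at 1.05. ATF4 and unfolded protein genes gave 12 higher, 8 lower and 7 not called of 27 (14 and 8 alone, median 0.20, adjusted p = 0.0767), with the cystine carrier SLC7A11 at 1.51 and STC2 at 1.18. Nucleic acid sensors gave 4 higher, 3 lower and 11 not called of 18 (median 0.071, adjusted p = 0.761), with RELA at -0.57. p53 targets gave 10 higher, 5 lower and 15 not called of 30 (median 0.057, adjusted p = 0.197), with CCNG1 at 0.59. Germline genes gave 2 higher, 1 lower and 10 not called of 13 (1 and 1 alone, median 0.014, -0.15 under quantile scaling, adjusted p = 0.767), with TEX15 at 0.53. Protocadherins gave 1 higher, 1 lower and 21 not called of 23 (median 0.49, adjusted p = 0.574), with PCDHGC3 at -0.74. Epithelial genes gave 3 higher, 6 lower and 11 not called of 20 (median 0.028 but mean -0.19 and median -0.035 under quantile scaling, adjusted p = 0.574), with the keratin genes KRT19 at -3.47 and KRT8 at -2.44. Neuronal genes gave 8 higher, 7 lower and 11 not called of 26 (9 and 7 alone, median 0.26, adjusted p = 0.708), with INSM1 at 1.43, MAPT 2.60-fold higher and NEFM at -0.84. Kidney and adrenal markers gave 4 higher, 3 lower and 5 not called of 12, with WT1 at -1.35. Gastric genes gave 1 higher of 7 with SST at least 6.18-fold higher, intestinal genes 1 higher and 1 lower of 7 with LGR5 at -0.50, and immune genes 1 higher of 4 with ITGAM 4.65-fold higher. The intestinal median of 0.055 turned to -0.11 under quantile scaling.

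In total 3271 genes were higher and 3927 lower with L760A, of 17960, and 45.4% of the called genes were higher, or 55.4% with total reads as the scaling. Libraries were separated for 49.4% of genes against 10% by chance. Chromosome 11 stood out, with a median of -0.56 over 649 genes and 87.5% of them below 0 (95% interval -0.60 to -0.52). RELA, on that chromosome, is therefore not a clean sign of lower NF-kB signalling. RRM1, BRMS1 and WT1 lie there too, and their falls may hold part of that shift.

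KO-labelled and L760A libraries of HEK293 shared part of their changes against the same WT libraries. CALCB, a calcitonin gene-related neuropeptide, rose from 156.3 ± 7.51 to 2230 ± 199 and 1631 ± 65.4 (log2 fold changes 3.82 and 3.38), and the hemidesmosome collagen gene COL17A1 by 3.26 and 3.20. The neurotrophin receptor NTRK2 rose by 2.82 and 3.34, NCKAP5 by 2.86 and 2.99, the mesoderm factor T by 2.86 and 2.85, SSPO by 3.37 and 2.78, SCUBE1 by 3.81 and 2.76 and LRRN1 by 4.07 and 2.71. LCP1 fell by 3.94 and 3.37. The Wnt receptor gene FZD10 was at least 13.7-fold and 14.1-fold lower and the netrin receptor gene UNC5D at least 12.8-fold and 13.1-fold lower. ZNF320 had ratios of 26.8 (7.11 to 227) and 55.0 (9.51 to 2.21e+03), ZNF347 43.8 (7.5 to 1.76e+03) in KO-labelled libraries and at least 15-fold in L760A, and ZNF816 38.4 (6.54 to 1.55e+03) and at least 13.1-fold.

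Of the genes called in the HEK293 pair, 1911 were higher in both and 2311 lower in both, where 876 and 1038 were the numbers for independent lists, and 827 went in opposite directions. Log2 fold changes had r = 0.426 and rho = 0.469 over all genes. In 100 simulations with no effect but with shared controls, the mean number of shared calls was 0.07 higher and 0.01 lower and the highest was 2. Without an effect few genes are called at all, so these counts cannot show how much shared controls add to the overlap. The covariance of the fold changes was 0.281 against 0.0502 in those simulations, while r there averaged 0.477, so the correlation alone carried no information. The 3 WT libraries could not be divided into separate controls, and part of the excess may come from the shared controls.

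**Figure D3:**
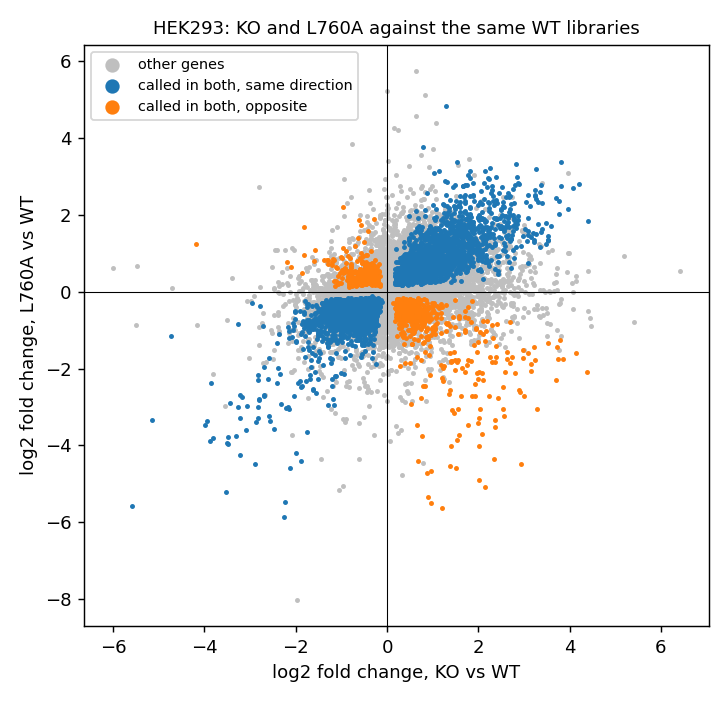
Log2 fold change of each gene in HEK293 libraries labelled KO and in L760A, both against the same WT libraries. Blue genes were called in both in the same direction and orange genes in opposite directions.

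Set directly against the libraries labelled KO, L760A libraries differed in single neural and matrix genes and in MYC. FAM155A stood at 119.5 ± 11.3 against 0.270 (ratio 355, 63.3 to 1.4e+04; n = 3 each) and the synaptic gene NRXN3 had a ratio of 290 (51.7 to 1.15e+04). SPARC, a collagen-binding matrix protein, was 55.8-fold lower in L760A (9.51 ± 2.49 against 575.5 ± 25.6), and the plexin-domain gene PLXDC2 was 80.3-fold lower (2.26 ± 1.04 against 250.8 ± 8.56, adjusted p = 2.81e-15). MYC was 6.41-fold higher (988.6 ± 21.4 against 153.6 ± 9.92).

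More genes separated the HEK293 mutants. CXCL1 was 34.8-fold higher in L760A (80.8 ± 2.89 against 1.37 ± 0.395), TNFRSF9 19.6-fold, TNF 15.6-fold and IL7 at a ratio of 26.6 (8.8 to 132), while KRTAP19-1 and MAGEB2 were each at least 23.4-fold higher. FLRT2 had a ratio of 360 (99.2 to 2.98e+03) in the direction of lower L760A values, TMEM47 159 (54.1 to 774), and JAKMIP2 and the arginine carrier SLC7A3 were at least 123-fold and 102-fold lower. SERPINB9 had a ratio of 116 (39.5 to 567), lower in L760A. HIST1H2BG was 113-fold and HIST1H3F at least 179-fold lower, and IPO5P1 had a ratio of 281 (50.0 to 1.11e+04). SSU72P4 was at least 71.5-fold lower and SLX1B-SULT1A4 higher (4.81, adjusted p = 0.034), and these last 5 share reads with copies. The neurofilament gene NEFM was 633.5 ± 11.2 against 117.9 ± 16.3, and ZNF100 and ZNF254 were 32.5-fold and 20.2-fold lower in L760A.

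Ribosomal protein genes were higher in L760A than in libraries labelled KO, 72 higher, 2 lower and 4 not called of 78 (median 0.76, camera adjusted p = 4.89e-33, lost at adjusted p = 0.0663 with an estimated correlation), with RPL22 at 1.52 and RPL8 at 7579 ± 213 against 2902 ± 90.5. Ribosome biogenesis genes gave 25 higher, 0 lower and 1 not called of 26 (median 0.72, adjusted p = 9.74e-15), with NOLC1 at 2042 ± 14.6 against 998.1 ± 14.5. TNRC18 neighbours gave 17 higher, 1 lower and 2 not called of 20 (median 0.69, adjusted p = 9.75e-07), but with position removed that call was lost (median 0.053, adjusted p = 0.855, test direction down). Cholesterol synthesis gave 18 lower, 2 higher and 4 not called of 24 (18 and 3 alone, median -0.58, adjusted p = 9.75e-07), with TM7SF2 at -1.99. TM7SF2 lies on chromosome 11, whose median was -0.706 in this comparison. Lists that lost their call with an estimated correlation were ATF4 targets (17 higher, 1 lower and 9 not called of 27, median 0.40, 8.1e-05 to adjusted p = 0.0663; STC2 at 1.89), neuronal genes (11 higher, 4 lower and 11 not called of 26, median 0.92, 0.0121 to 0.0663; SYP at 1.71, TUBB3 at 1.49) and histone genes (7 higher, 34 lower and 19 not called of 60, median -0.53, 1.42e-06 to 0.297).

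The same held for interferon-stimulated genes in L760A against libraries labelled KO (3 higher, 15 lower and 17 not called of 35, median -0.33). The camera adjusted p was 0.0173, and 0.0663 with an estimated correlation. IFITM3, on chromosome 11, stood at -3.26, OAS3 at -1.89, IFI6 at 1.12 and IRF1 at 1.26. Cell cycle genes gave 19 higher, 7 lower and 11 not called of 37 (median 0.22, adjusted p = 0.0212 and 0.0663 with an estimated correlation, lost under 3 other scalings), with E2F2 at 1.77 and RRM1, on chromosome 11, at -0.86 but 0.28 with position removed (adjusted p = 0.000425). Epithelial genes gave 2 higher, 8 lower and 10 not called of 20 (median -0.43, adjusted p = 0.0359 and 0.239 with an estimated correlation, lost under 3 other scalings), with the splicing factor ESRP1 at -4.50 and KRT19 at -4.12. Mesenchymal genes gave 6 higher, 13 lower and 9 not called of 28 (median -0.35, adjusted p = 0.0423 and 0.239 with an estimated correlation, lost with GC correction or total reads), with MMP2 at -2.44 and FN1 at 1019 against 2652. In all, 4044 genes were higher and 4121 lower of 17960, 49.5% of the called genes higher, or 41.7% with total reads as the scaling. The chromosome medians were 0.59 for chromosome 7 and -0.71 for chromosome 11, so position accounted for part of the contrast, and 65.5% of calls were kept after it was removed.

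**Figure D4:**
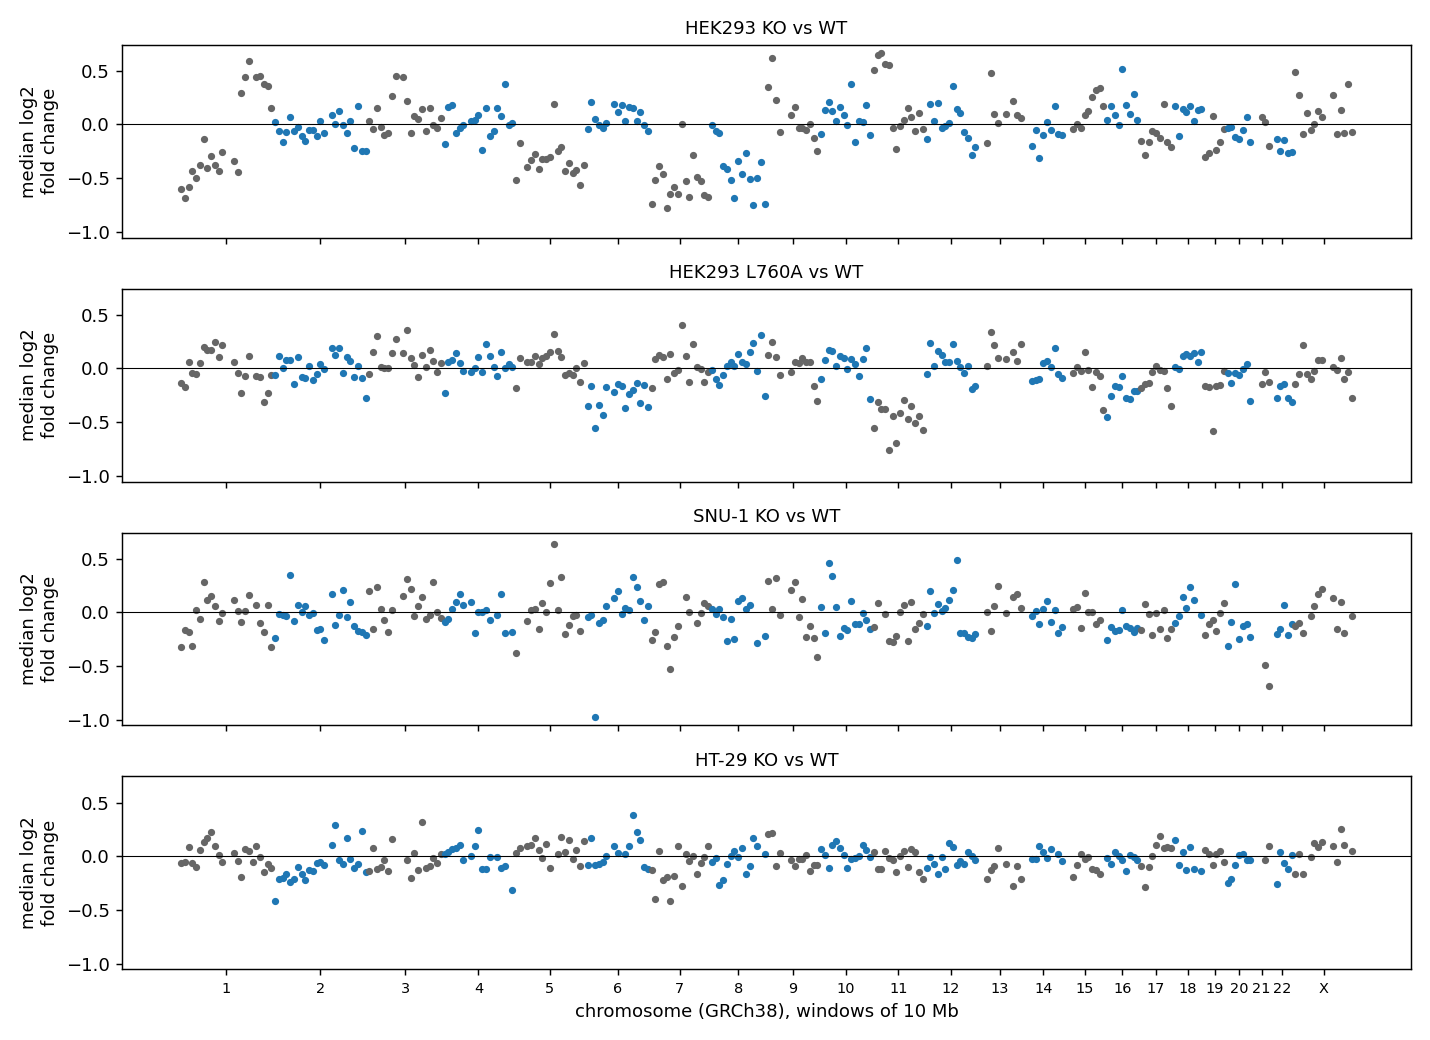
Median log2 fold change of genes in 10-Mb windows along the chromosomes in 4 comparisons.

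In SNU-1 libraries labelled KO cell cycle genes fell and ATF4 targets rose. RRM2, which supplies deoxynucleotides for replication, fell 11.5-fold from 3486 ± 7.74 to 301.5 ± 13.4 (n = 3 each, adjusted p = 3.69e-34), and the proliferation marker MKI67 fell from 6704 ± 90.6 to 1677 ± 47.8. SERPINA3, an acute phase protease inhibitor, rose 29.9-fold from 42.1 ± 5.24 to 1282 ± 23.4, and DDIT4, a stress-induced inhibitor of mTORC1, 18.2-fold from 92.4 ± 8.83 to 1694 ± 39.2. ASNS, the asparagine synthetase that ATF4 induces, rose 6.73-fold from 263.9 ± 24.1 to 1777 ± 62.4.

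Other large changes in SNU-1 libraries labelled KO were those of single genes. HLA-DMA, which loads peptide on class II molecules, rose 17.8-fold (2.62 ± 1.44 to 59.6 ± 0.390) and the retinoic acid hydroxylase CYP26B1 15.6-fold (4.34 ± 1.30 to 80.8 ± 8.06). The cytokine receptor IL21R, the spindle protein MISP and the peptide receptor NPY4R had no WT read and were at least 24.6-fold, 17.9-fold and 18.6-fold higher. SERPINA5 had a pooled ratio of 25.6 (8.43 to 127), UBXN8 rose from 1.65 ± 0.542 to 41.5 ± 10.3 and the small nucleolar RNA SNORD97 at least 30.2-fold. Losses included CREB3L1, a secretory pathway factor (84.4 ± 5.65 to no reads, at least 80.7-fold), the reductase gene DHRS2 (40.9-fold, 1278 ± 4.40 to 30.7 ± 6.08, adjusted p = 1.34e-26) and the desmosome genes DSG2 (35.8-fold, 161.1 ± 4.93 to 4.18 ± 2.88) and PKP2 (ratio 73.1, 19.9 to 609). SHROOM3, which constricts the apical side of epithelia, fell 30.7-fold, FOXP2 had a ratio of 62.7 (17.0 to 523), and GRIN2A and the defensin gene DEFB1 were at least 28.5-fold and 23.1-fold lower. HIST1H2BM (ratio 95.9, 16.8 to 3.83e+03) and HBA1 (-5.29, adjusted p = 0.01) also fell, with copies that make their reads uncertain.

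All 37 cell cycle genes were lower in SNU-1 libraries labelled KO, as they were alone (median -1.86, camera adjusted p = 5.11e-28), with MCM4 at -2.11 and MCM7 at -1.86. Histone genes, whose RNA is made in S phase, gave 49 lower and 3 not called of 52 (median -1.71, adjusted p = 2.74e-28), with HIST2H2AA4 at 2329 ± 22.9 against 9092 ± 180.5 and HIST1H1B at -1.88, read with the caution for copies. Ribosome biogenesis gave 23 lower, 2 higher and 1 not called of 26 (median -1.01, adjusted p = 4.66e-13), with ODC1 at -1.68, NCL at -1.07 and NPM1 at -0.85. ATF4 targets gave 20 higher, 2 lower and 3 not called of 25 (median 0.97, adjusted p = 1.52e-09), with ASNS at 2.75 and the serine synthesis gene PHGDH at 1.39. Cholesterol synthesis gave 20 higher, 2 lower and 1 not called of 23 (21 and 2 alone, median 0.95, adjusted p = 1.71e-09). HMGCS1 rose 4.08-fold from 228.6 ± 14.9 to 934.4 ± 36.7, MSMO1 by 2.18, FDFT1 by 1.71 and SREBF2, the master regulator of the pathway, by 1.36. ZNF genes gave 148 higher, 48 lower and 170 not called of 366 (148 and 47 alone, median 0.20, adjusted p = 0.00344), with ZNF493 at 1.68 and ZNF106 2.64-fold higher.

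Several list calls in SNU-1 did not outlast an estimated correlation between genes. Mitochondrial genes gave 10 lower, 2 higher and 1 not called of 13 (median -1.01, camera adjusted p = 3.6e-06 and adjusted p = 0.329 with an estimated correlation), MT-ND2 went from 1.87e+04 ± 635 to 6151 ± 132, and the mitochondrial share from 2.93 ± 0.13% to 2.23 ± 0.03% of reads. Antigen presentation gave 12 higher, 2 lower and 5 not called of 19 (median 0.41, 0.00344 and adjusted p = 0.0776 with an estimated correlation), with TAPBP at 1.01. Mesenchymal genes gave 8 higher, 0 lower and 4 not called of 12 (median 0.75, 0.00344 and adjusted p = 0.0776 with an estimated correlation), where the YAP targets CYR61 (6.15-fold, 1248 ± 31.2 to 7677 ± 68.9) and CTGF (2.35) rose. p53 targets gave 17 higher, 6 lower and 5 not called of 28 (median 0.35, 0.00749 and adjusted p = 0.0776 with an estimated correlation), with TP53INP1 10.6-fold higher, ZMAT3 at 1.22 and SESN2 at 1.02. Protocadherins gave 8 higher, 0 lower and 5 not called of 13 (median 1.47, 0.0214 and adjusted p = 0.144 with an estimated correlation, 0.075 under quantile normalization), with PCDHB13 at 2.12 and PCDHGB2 at least 13.3-fold, the last with shared reads.

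Silencing genes in SNU-1 were not called as a list, 11 higher, 17 lower and 9 not called of 37 (12 and 17 alone, median -0.083, 0.029 under quantile scaling, camera adjusted p = 0.403). Within it the maintenance methylation gene UHRF1 fell 6.01-fold (1898 ± 38.9 to 315.1 ± 9.25), with DNMT3B at -2.59 and DNMT1 at -1.27, genes that also follow S phase. SIN3 and HDAC subunits gave 8 higher, 13 lower and 8 not called of 29 (median -0.0085, 0.12 under quantile scaling, adjusted p = 0.559), with GPS2 at -1.65 and RBBP4 at -0.73. Interferon-stimulated genes gave 15 higher, 8 lower and 8 not called of 31 (median 0.18, adjusted p = 0.401), with IFIT2 at 2.15, LGALS3BP at 1.66 and OAS3 at -1.77. Nucleic acid sensors gave 4 higher, 3 lower and 8 not called of 15 (median -0.053 but mean 0.035, positive under quantile scaling, adjusted p = 0.987), with MAVS at 0.56 and TREX1 at -0.91. LTR-derived genes gave 1 higher, 1 lower and 3 not called of 5 (median 0.20, -0.14 under quantile scaling), with ERV3-1 at 1.25 and ERVK3-1 at -0.35, and genes with LTR promoters 3 higher, 2 lower and 3 not called of 8 (median 0.19 but mean -0.42).

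The other SNU-1 lists were not called. Ribosomal protein genes gave 28 higher, 36 lower and 14 not called of 78 (median -0.051, 0.16 after GC correction, camera adjusted p = 0.454), with RPL3 at 0.45 and RPS2 at -0.33. Neighbours of TNRC18 gave 1 higher, 8 lower and 9 not called of 18 (median -0.090, 0.074 with position removed, adjusted p = 0.373), with DAGLB at -0.80 and ACTB at -0.48. Germline genes gave 5 higher, 3 lower and 4 not called of 12 (median 0.064 but mean -0.19 and median -0.12 under quantile scaling, adjusted p = 0.965), with TEX19 at 1.12 and STAG3 at -1.03. HOX genes gave 5 higher, 0 lower and 13 not called of 18 (median 0.40, adjusted p = 0.342). Epithelial genes gave 1 higher, 1 lower and 4 not called of 6 (median -0.042, positive after GC correction, with the test pointing up, adjusted p = 0.947), with EHF at 1.54 and KRT18 at -2.51. Neuronal genes gave 3 higher, 1 lower and 3 not called of 7, with RTN1 at 1.47 and SYP at -1.10 (median 0.068, -0.40 under quantile scaling). Intestinal genes had none called of 5 (median 0.024 but mean -0.28 and median -0.14 with position removed). Gastric genes gave 2 higher of 4, with MUC6 at 1.84, kidney and adrenal markers 1 higher of 2, with PAX8 higher, and the 1 immune gene tested was lower.

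In SNU-1 4136 genes were higher and 4314 lower of 14386 tested, 48.9% of the called genes higher, and libraries were separated for 63.5% of genes against 10% by chance. Chromosome 21 had the lowest median, -0.57 over 96 genes with 81.2% below 0 (95% interval -0.73 to -0.39).

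Among the largest changes in HT-29 libraries labelled KO were a mucin gene and genes of alcohol dehydrogenases. MUC5AC, a gel-forming mucin of stomach and airway, fell 14.2-fold from 6019 ± 137 to 422.6 ± 25.3 (n = 3 each, adjusted p = 2.84e-48), and the alcohol dehydrogenase gene ADH1C rose 35.7-fold from 38.3 ± 2.42 to 1400 ± 72.3. LGR5, the marker of intestinal stem cells, rose 7.35-fold from 10.5 ± 2.51 to 82.8 ± 9.94, and HOXB8 rose from 143.8 ± 7.88 to 657.9 ± 9.88.

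Other gains in HT-29 libraries labelled KO were PRUNE2, a BNIP2 family gene (1.15 ± 1.19 to 77.9 ± 10.7, 40.9-fold, adjusted p = 4.47e-15), ADH4 37.8-fold (2.46 ± 1.30 to 124.4 ± 27.0), the YAP paralog gene WWTR1 14.5-fold and MS4A8 14.4-fold. The guidance receptor ROBO1 rose 13.2-fold (21.1 ± 3.24 to 290.4 ± 25.5), KRT17, a keratin of stressed epithelium, 12.3-fold (9.32 ± 2.70 to 123.2 ± 7.33) and the connexin gene GJA1 with a pooled ratio of 39.6 (13.2 to 195). The lipid carrier gene ABCA12 and the sodium channel gene SCN9A were at least 13-fold and 12.7-fold lower. NEBL, an actin-binding gene, fell from 212.2 ± 26.6 to 14.3 ± 2.24 (-3.80) and ZNF141 with a ratio of 48.2 (8.28 to 1.94e+03). Uncertain for shared sequence were ZBTB45P2 and ZFP91-CNTF (each at least 24.8-fold higher), POTEF (20.4-fold lower), POTEE (-3.85), MAGEA3 (ratio 63.0, 10.9 to 2.53e+03, lower) and IPO5P1 (at least 14.5-fold lower).

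Ribosomal protein genes were lower in HT-29 libraries labelled KO, 70 lower, 2 higher and 5 not called of 77 (72 and 2 alone, median -0.996, camera adjusted p = 5.06e-61). RPL13A fell from 4858 ± 147 to 1985 ± 90.6 (-1.29) and RPS4X from 1327 ± 50.2 to 430.8 ± 15.9, with RPS2 at -1.20 and RPL10 at -1.16. Interferon-stimulated genes gave 29 higher, 1 lower and 10 not called of 40 (31 and 1 alone, median 0.67, adjusted p = 1.42e-11), with PARP14 at 1994 ± 41.7 against 1191 ± 26.3, IFI6 at 1.21 and PLSCR1 at 0.76. HOX genes gave 13 higher, 0 lower and 11 not called of 24 (13 and 1 alone, median 0.58, adjusted p = 7.32e-07), with HOXB8 at 2.19, HOXB6 at 1.12 and HOXB3 at 1.05. Mitochondrial genes gave 12 higher and 1 not called of 13 (13 alone, median 0.68, adjusted p = 2.95e-17 and adjusted p = 0.26 with an estimated correlation), with MT-CO2 at 0.83, and their share of reads was 10.7 ± 0.52% against 7.38 ± 0.618%.

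Other HT-29 lists lost their call with an estimated correlation. Mesenchymal genes gave 4 higher, 0 lower and 8 not called of 12 (median 0.41, camera adjusted p = 0.0259 and adjusted p = 0.26 with an estimated correlation), with CTGF 6.64-fold higher (59.7 ± 5.92 to 401.6 ± 39.5). Antigen presentation gave 2 higher, 9 lower and 10 not called of 21 (median -0.23 but mean 0.029, 0.0259 and adjusted p = 0.298 with an estimated correlation, 0.0534 after GC correction), with the chaperone CALR at -0.89 and PDIA3 at -0.64, while HLA-DMB rose 11.5-fold (4.46 ± 1.17 to 61.3 ± 10.5). Intestinal genes gave 8 higher, 2 lower and 4 not called of 14 (median 0.32, 0.0259 and adjusted p = 0.269 with an estimated correlation, 0.0548 with position removed), with LGR5 at 2.88, MUC13 at 1.37 and HNF4A at 0.67 but CEACAM6 at -2.94. Nucleic acid sensors gave 7 higher, 0 lower and 11 not called of 18 (median 0.24, 0.0351 and adjusted p = 0.364 with an estimated correlation), with DHX58 at 1.48 and DDX58, the RIG-I gene, at 1.01.

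Chromatin and retroviral lists were not called in HT-29. H3K9 silencing genes gave 15 higher, 6 lower and 16 not called of 37 (16 and 6 alone, median 0.11, camera adjusted p = 0.0837), with BAHCC1, a paralog of TNRC18, at 0.73 and ATRX at 0.68. SIN3 and HDAC subunits gave 7 higher, 7 lower and 13 not called of 27 (median 0.0056, negative under other scalings). LTR-derived genes gave 0 higher, 1 lower and 6 not called of 7 (median -0.14), and genes with LTR promoters 4 higher, 2 lower and 11 not called of 17 (median 0.011, negative with total reads as scaling), with B3GALT5 at -2.10. ZNF genes gave 43 higher, 35 lower and 276 not called of 354 (38 and 30 alone, median 0.026 but mean -0.040 and median -0.048 with total reads), with ZNF292 at 0.73 and ZNF506 at -1.95. Germline genes gave 1 higher, 3 lower and 6 not called of 10 (2 and 3 alone, median -0.36), with REC8 at 1.19. MAGEA12 and MAGEA6 were at least 11.1-fold and 8.65-fold lower, with shared reads. Protocadherins gave 2 higher, 1 lower and 5 not called of 8, with PCDHGA10 at 0.96. Neighbours of TNRC18 gave 3 higher, 5 lower and 10 not called of 18 (median -0.056, 0.11 with position removed), with AP5Z1 at 0.64 and ACTB at 0.26.

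Growth and stress lists were not called in HT-29 either. Ribosome biogenesis gave 4 higher, 6 lower and 16 not called of 26 (5 and 6 alone, median -0.018, 0.052 after GC correction, camera adjusted p = 0.596), with the nucleolar methyltransferase FBL at 176.2 ± 10.9 against 361 ± 16.6 and NCL at 0.19. Cell cycle genes gave 4 higher, 12 lower and 21 not called of 37 (median -0.092, adjusted p = 0.513), with MKI67 at 1.33 and TOP2A at 0.58 but MCM3 at -0.57 and CDC20 at -0.83. ATF4 and unfolded protein genes gave 7 higher, 13 lower and 6 not called of 26 (7 and 14 alone, median -0.18, adjusted p = 0.121), with ATF3 at 1.47, HSPA5 at -0.62 and HSP90B1 at -0.74. p53 targets gave 9 higher, 4 lower and 14 not called of 27 (10 and 4 alone, median 0.12, adjusted p = 0.128), with BTG2 6.26-fold higher, CDKN1A at 1.55 and PLK2 at -0.85. Cholesterol synthesis gave 2 higher, 1 lower and 20 not called of 23 (2 and 0 alone, median 0.064, -0.0078 with total reads). Epithelial genes gave 10 higher, 9 lower and 8 not called of 27 (11 and 9 alone, median 0.0088 but mean -0.18, negative under 3 other settings), with KRT8 at 0.96. Histone genes gave 11 higher, 21 lower and 30 not called of 62 (12 and 23 alone, median -0.084, 0.038 after GC correction, adjusted p = 0.212), with HIST2H2BE at 0.98 and HIST1H4C at -1.27. Neuronal genes gave 0 higher and 3 lower of 5, with MAP2 at -1.33. Gastric genes gave 1 higher and 1 lower of 4, with GATA6 at 0.21 and MUC5AC at -3.83, kidney and adrenal markers 2 higher of 3, and immune genes 1 higher of 2 (both alone), with LYZ at 0.79.

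In HT-29 2477 genes were higher and 2327 lower of 15052 tested, 51.6% of the called genes higher, but 39.6% with total reads as the scaling. Libraries were separated for 42.7% of genes against 10% by chance. No chromosome stood out, the lowest median being -0.13 for chromosome 13.

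Some genes were called in the same direction in all 3 lines labelled KO. ABAT, which breaks down GABA, had log2 fold changes of 2.15, 2.19 and 1.73 in HEK293, SNU-1 and HT-29 (n = 3 each), and the cullin adaptor gene KLHL3 1.84, 3.15 and 1.47. FLT3LG, a growth factor of dendritic cells, had 1.19, 2.56 and 2.18, PLD1 2.08, 1.08 and 1.60, ADAMTS7 2.49, 1.26 and 1.31, TP53INP2 1.74, 1.79 and 1.36, SEMA6A 1.58, 1.47 and 1.09, FRMD4B 1.28, 1.55 and 1.13, CYP2E1 1.81, 1.07 and 1.16 and PRUNE2 2.08, 1.54 and 5.35. The synaptic vesicle gene CPLX1 fell by 2.20, 2.06 and 1.63, and the mitochondrial genes MTFP1 by 1.33, 1.14 and 2.14, PPIF by 1.22, 2.19 and 1.08 and C1QBP by 1.44, 1.02 and 1.09. DHRS2 fell by 1.12, 5.35 and 1.75, ECE2 by 1.63, 1.74 and 1.08, NME2 by 1.07, 1.10 and 1.97, FBL 2.31-fold, 2.19-fold and 2.04-fold, RDH10 by 1.23, 1.09 and 0.97 and HIST2H3D, with shared reads, by 1.07, 1.57 and 1.61.

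Over 12266 genes tested in each line, 357 were higher in all 3 and 620 lower in all 3, 2.85 and 2.59 times the 125 and 240 for independent lists. HEK293 and SNU-1 shared 1482 higher (866 for independent lists, Fisher one-sided p = 1.65e-162) and 2524 lower (1393) with 1114 opposite and r = 0.34 between fold changes. HEK293 and HT-29 shared 762 higher (549, p = 9.49e-29) and 1044 lower (714, p = 1.92e-57) with 1108 opposite and r = 0.094, and SNU-1 and HT-29 751 higher (585, p = 1.96e-18) and 892 lower (679, p = 4.65e-27) with 1223 opposite and r = 0.066. Whether expression level adds to these overlaps was not tested. A difference in the KO-labelled effect between lines, tested by an edgeR interaction on recovered reads, was called for 5510 genes (44.9%) between SNU-1 and HEK293, 5208 (42.4%) between HT-29 and HEK293 and 5755 (46.9%) between HT-29 and SNU-1, of 12274.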

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

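The interaction between lines, the copy number comparison, the comparison across lines for chromosome 7, the ribosome biogenesis comparison and the test for exchanged libraries were chosen after the results were seen; for the GC content, scaling and split tests the limits were written before those tests were run.

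Some effects of the KO label differed between lines by the edgeR interaction test on recovered reads, with the difference in log2 fold change and its adjusted p given here. SNU-1 minus HEK293 was -1.02 for TNRC18 (1.98e-11), -1.04 for PLD1 (0.0101), -4.39 for DHRS2 (4.17e-20), -1.09 for PPIF (3.02e-10) and 0.298 for C1QBP (0.00594). HT-29 minus SNU-1 was 4.33 for PRUNE2 (2.66e-13) and -2.28 for KLHL3 (0.00138), and HT-29 minus HEK293 was -1.36 for ADAMTS7 (0.0173) and -0.769 for HIST2H3D (0.00991). Apart from TNRC18 these genes moved the same way in each line, and the size of the change differed between the 2 lines given. That pair is the called one with the largest difference. PRUNE2 and DHRS2 were called in every pair. PLD1, PPIF, C1QBP, KLHL3, ADAMTS7 and HIST2H3D also had pairs without a call, as for HT-29 minus SNU-1 in ADAMTS7 (-0.125, 0.865) and HIST2H3D (-0.101, 0.752).

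Lists differed between lines by camera with an estimated correlation on the same recovered reads. The median difference of the members is given with its adjusted p, for the called pair of lines with the largest difference. Other pairs could be called too, as cell cycle for SNU-1 minus HEK293 (-1.69, 5.49e-08). HT-29 minus HEK293 was not called for cell cycle (0.0715, 0.155) or histone genes (0.0341, 0.744), nor HT-29 minus SNU-1 for neighbours of TNRC18 (0.0482, 0.725). SNU-1 minus HEK293 was -0.111 for H3K9 silencing (0.013), -0.31 for interferon-stimulated genes (0.0376), 0.521 for neighbours of TNRC18 (0.0292), 1.2 for cholesterol synthesis (6.69e-06) and 0.658 for mesenchymal genes (0.013). HT-29 minus SNU-1 was -1.15 for antigen presentation (0.00421), 1.74 for cell cycle (1.02e-07), -1.44 for ATF4 targets (9.98e-05), 1.6 for histone genes (0.0144) and -0.911 for ribosomal protein genes (0.00684), and HT-29 minus HEK293 was 1.13 for ribosome biogenesis (9.98e-05). Lines were grown in different media and edited separately, and the cause was not tested.

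Chromosome 7 genes were lower in HEK293 libraries labelled KO. A loss of copies could lower them, since 84.1% of the genes lay below 0 and 15 of 16 windows had a negative median. GC content and length do not account for it, as the chromosome median was still -0.557 (-0.602 to -0.518) once their trend was removed. A TNRC18 effect in every line was argued against by chromosome 7 medians of -0.0652 in HT-29 and -0.0369 in SNU-1. DNA was not measured, so copy number and a regional effect in this set of cells stay open.

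Ribosomal protein genes were lower in HEK293 and HT-29 libraries labelled KO. With an estimated correlation between genes the camera call was lost in HEK293 (adjusted p = 0.0832) and kept in HT-29 (0.0337). In HEK293 the difference to genes matched for GC content, length and expression was -0.238 (-0.315 to -0.123) and the median nearest 0 under other scalings was -0.299, so both may account for part of the shift. The ribosome biogenesis list was lower there as well (-1.24), as a lower growth program would give. That list also fell in L760A (-0.668) and SNU-1 (-1.01), where ribosomal protein medians were 0.157 and -0.051. Lower biogenesis genes therefore did not always come with lower ribosomal protein genes. In HT-29 the median nearest 0 under other scalings was -1.01 and ribosome biogenesis was near 0 (-0.0177), so neither accounts for it. The matched difference there was -0.943 (-1.09 to -0.719). Matching used the longest annotated transcript of each gene, which need not be the one expressed. Matched genes were also longer, with a median length of 2329 against 1857. Genes matched in this way did not fall alike, but an effect of the expressed length stays open. RNA stability and library preparation stay open.

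TNRC18 RNA was not called lower in the HEK293 and HT-29 libraries labelled KO, but in HEK293 this turned to -0.22 (limma adjusted p = 0.000382) with GC content and length removed. The TNRC18 values argue against a single exchanged library as the reason. The lowest libraries labelled KO stood at 1482.7 in HEK293 and 2281.1 in HT-29, above the WT means of 1471.9 and 2240.0. Each of the 21 libraries was also closest to its own group, with a smallest margin of 0.0242. A whole group under a wrong label, or a deletion that leaves most of the transcript, stays open, as read positions were not analysed here.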

How the results depend on the processing

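The tests edgeR, DESeq2, total reads, GC content and length, and chromosome position were added after the results were seen; the other settings were planned. Lists were followed only where limma and camera called them.

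Asking for a log2 fold change of at least 1 left 2106 higher and 948 lower in HEK293 KO, 1015 and 557 in L760A, 1366 and 970 in SNU-1, 455 and 484 in HT-29 and 714 and 1481 (2195 in all) for L760A against KO. Shared calls came down to 13 higher and 9 lower over 3 lines and to 577 and 140 for KO with L760A. In that order of comparisons limma called 9555, 7198, 8450, 4804 and 8165 genes, edgeR 9557, 7255, 8484, 4828 and 8261, and DESeq2 fewer, 8195, 5913, 7616, 3727 and 6935, keeping 85.3, 81.6, 90.0, 77.4 and 84.5% of the limma calls.

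TNRC18 depended on the setting. In HEK293 KO its log2 fold change was 0.44 with quantile normalization (limma adjusted p = 0.000665), 0.35 with total reads (0.00104), 0.82 with position removed (1.53e-07) and -0.22 with GC content and length removed (0.000382), the reverse direction. Leaving out a library gave 0.091 to 0.28, called without KO replicate 2 or WT replicate 1. In L760A the GC correction gave -0.14 (0.0276) in place of 0.011. In HT-29 removal of position gave 0.21 (4.1e-06), or 0.24 with full windows (3.66e-07). For L760A against KO it was -0.31 with quantile normalization (0.0095), -0.18 with 6 libraries (0.0207), -0.26 with total reads (0.0127) and -0.80 with position removed (1.62e-07). Leaving out a library gave -0.27 to -0.14 there, called without KO replicate 2 (0.0106). In SNU-1 it stayed lower in each setting.

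With a replicate block, pairing libraries by number, TNRC18 had 0.20 in HEK293 KO (adjusted p = 0.0259) and -0.18 for L760A against KO (0.0398), both past the threshold they miss without it. The block gave 4864 higher and 4861 lower in HEK293 KO, 3391 and 4077 in L760A, 4108 and 4301 in SNU-1, 2387 and 2290 in HT-29 and 8433 for L760A against KO. Same-number libraries were not paired by the correlation rule, so the block has no known basis. The cause was not tested.

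Removing the running median along chromosomes kept 77.5, 77.5, 89.7, 86.6 and 64.5% of calls with windows that shrink at chromosome ends, and 78.0, 78.8, 90.7, 87.9 and 65.5% with full windows there. Calls in the opposite direction were 76, 22, 17, 0 and 147, or 78, 18, 12, 0 and 148. Shrinking windows removed the change of genes at an end from itself: CYP2E1 in SNU-1 became -3.78e-05 but was 1.12 with full windows, and MID1 for L760A against KO became 0.041 but was -0.24, so neither reversal counts. ADAR in HEK293 KO (0.040), RELA in L760A (0.13) and RRM1 for L760A against KO (0.28, limma adjusted p = 0.000425) turned either way, and so did the TNRC18 neighbours for L760A against KO by the camera direction, with their call lost (median 0.064, or 0.053 with full windows). Other lists that lost their call either way were neighbours (-0.078) and cholesterol synthesis (-0.33, -0.38) in HEK293 KO, HOX (0.16) and mesenchymal genes (0.31, 0.32) in L760A and intestinal genes (0.24) in HT-29. Antigen presentation (-0.21) and mesenchymal genes (0.49) in HT-29 lost it with shrinking windows alone.

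Scaling removed some list calls. Quantile normalization lost cell cycle (-0.16) and cholesterol synthesis (-0.23) in HEK293 KO, interferon-stimulated genes (0.36) and cell cycle (-0.095) in L760A, protocadherins (1.39) in SNU-1, and cell cycle (0.13) and epithelial genes (-0.30) for L760A against KO. GC correction lost cholesterol synthesis (-0.24) in HEK293 KO, cell cycle (-0.14) in L760A, antigen presentation (-0.20) in HT-29, and cell cycle (0.13), epithelial (-0.34) and mesenchymal genes (-0.33) for L760A against KO. In that last comparison 6 libraries lost epithelial (-0.43) and mesenchymal genes (-0.35), and total reads lost cell cycle (0.14), epithelial (-0.50) and mesenchymal genes (-0.42). Total reads moved the share of called genes that were higher from 50.3 to 63.7% in HEK293 KO, 45.4 to 55.4% in L760A, 51.6 to 39.6% in HT-29 and 49.5 to 41.7% for L760A against KO. Quantile normalization kept 79.0% of HEK293 KO calls and called 32 genes in the opposite direction, and GC correction 22 there and 26 in SNU-1.

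An estimated correlation between genes left medians as they were and lost these calls: in HEK293 KO HOX (0.41), p53 (0.28), cholesterol (-0.40), mesenchymal (0.48) and ribosomal protein genes (-0.67); in L760A interferon-stimulated (0.42), HOX (0.30), cell cycle (-0.23), ribosome biogenesis (-0.67), mesenchymal (0.42), histone (-0.79), mitochondrial (0.34) and ribosomal protein genes (0.16). In SNU-1 it lost antigen presentation (0.41), protocadherins (1.47), p53 (0.35), mesenchymal (0.75) and mitochondrial genes (-1.01), and in HT-29 nucleic acid sensing (0.24), antigen presentation (-0.23), mesenchymal (0.41), intestinal (0.32) and mitochondrial genes (0.68). For L760A against KO it lost interferon-stimulated (-0.33), cell cycle (0.22), ATF4 (0.40), neuronal (0.92), ribosomal protein (0.76), epithelial (-0.43), mesenchymal (-0.35) and histone genes (-0.53).

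Leaving out each library gave 4177 to 4689 higher and 4323 to 4686 lower in HEK293 KO, 2670 to 3332 and 3406 to 4049 in L760A, 3771 to 3915 and 4065 to 4164 in SNU-1, 2102 to 2203 and 1871 to 2150 in HT-29 and 7152 to 7567 for L760A against KO. List medians ran from 0.32 to 0.53 for HOX in HEK293 KO and 0.18 to 0.47 for mitochondrial genes in L760A, each lost without WT replicate 1. In HT-29 antigen presentation ran from -0.27 to -0.20, lost without WT replicate 1, and nucleic acid sensing from 0.21 to 0.29, lost without KO replicate 1 or 3. Mesenchymal genes for L760A against KO ran from -0.40 to -0.23, lost without KO replicate 1 or L760A replicate 3. SLX1B-SULT1A4 lost its call under several settings and HBA1 in SNU-1 with a pseudocount of 0.1.

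Each pair of groups can be split 10 ways, too few for a share under 0.05, and 1 split was as large as the real one, itself. The real split called 9555, 7198, 8450, 4804 and 8165 genes, and the highest other split 0, 1, 2, 2 and 0. Each other split mixes libraries of both groups, so the difference between groups enters its spread and few calls follow. The low counts therefore do not measure how often chance alone gives as many calls.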

Other observations

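The test on ZNF genes was chosen after ZNF genes were seen among the strongest shared losses of the HEK293 mutants, so its p restates that view and is given as a description. Of 52 genes lowered at least 4-fold in both libraries labelled KO and L760A 12 were ZNF genes, 23.1% against 2.32% of the other 17908 genes (Fisher p = 2.44e-09). ZNF558 had log2 fold changes of -3.22 and -3.29, ZNF83 -3.18 and -2.74 and ZNF681 -3.06 and -2.97, next to ZNF320, ZNF347 and ZNF816. Most of the 12 lie on chromosome 19, several of them side by side, with ZNF595 on chromosome 4 and ZNF736 on chromosome 7, and neighbours are not independent. The 3 WT libraries are the control of both mutants, and ZNF genes share sequence, so the cause stays open.

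Chromosome medians moved in other groups as measured facts. In L760A chromosome 11 had -0.558 (87.5% of 649 genes below 0), chromosome 6, which carries the HIST1 genes, -0.298 (74.9%) and chromosome 16 -0.295 (75.8%). In HEK293 libraries labelled KO chromosome 8 had -0.416 (76.1% below 0) and chromosome 5 -0.358 (74.3%), and in SNU-1 chromosome 21 had -0.567 (81.2% of 96 genes below 0). DNA was not measured, and the cause was not tested for these.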
